A study of Rattus norvegicus with 72 samples.

How the data were processed

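The 72 libraries come from male Sprague-Dawley rats, 24 each from microdissected glomeruli, microdissected S1 proximal tubules and whole left kidney, in 18 groups of 4 by tissue, surgery (right nephrectomy or sham) and time (24, 48 or 72 h). Per the labels, RNA of the dissected segments was isolated with a Zymo Quick-RNA kit, amplified with NuGEN Ovation RNA-seq V2 and sequenced from 1 end, while whole kidney RNA was isolated with Qiagen RNeasy, made into strand-specific libraries with Illumina TruSeq Stranded HT and LT kits and sequenced from both ends. Which whole kidney library was made with which of these kits is not given in the sources used here, so a kit effect was not tested. The labels do not say whether the libraries of a group come from separate rats, so p-values measure the spread between these libraries, which may in part be technical.

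The deposited count tables hold whole-number read counts per gene, made with Trimmomatic 0.32, STAR 2.4.0.1, SAMtools and HTSeq, per the submitters' processing notes. The versions of SAMtools and HTSeq, the genome build, the annotation release and the use of strand in counting are not given in the sources used here. Reads of overlapping genes and of near-identical copies, such as histone genes, may be counted for another gene or for none, and such values are uncertain. The authors also deposited RPKM values for glomeruli and S1 tubules and FPKM values for whole kidney, per the file headers. Where a gene had over 20 counts, these values were checked to be the deposited counts divided by the library's gene total and by a constant per gene: the largest coefficient of variation of that constant was 4.04e-09 over 21280 genes for RPKM and 8.37e-09 over 14609 genes for FPKM. Each table has 32545 genes with an Ensembl gene ID and a symbol, and 4708 of them share their symbol with another ID. The files give no positions, so none are printed.

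The 5 HTSeq summary entries, which name no gene, were kept out of library totals and tests. Gene counts made up 2.9 to 65.8% of uniquely placed reads in glomeruli (median 26.95), 8 to 77.4% in S1 tubules (62.9) and 60.2 to 88.4% in whole kidney (76). Reads without a unique placement made up 34.8 to 59.7% of all reads in glomeruli, 31.5 to 53.9% in S1 tubules and 32.1 to 93.9% in whole kidney. The 37 mitochondrial genes took 9.9 to 51.2%, 22.1 to 72.3% and 36 to 80.6% of gene counts. No library fell under 1e+06 gene counts (0 of 72), and none was left out of the main tests. Among 108 pairs of libraries of a group, compared over genes with at least 20 counts, no column was a copy of another (smallest chi-square per degree of freedom 5.99). Counts are of amplified fragments without molecular identifiers, so the errors given are those between libraries and not counting errors.

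Tests ran in R 4.3.3. For each tissue, edgeR 4.0.16 was fitted to the 24 libraries with a mean for each of the 6 groups of surgery and time, TMM normalization and filterByExpr (minimum count 10). Its quasi-likelihood F test compared nephrectomy with sham at each time, as the mean of the 3 times, and for a difference of the effect between times. The difference of the mean effect between glomeruli and S1 tubules was tested in a fit of those 48 libraries. Whether a glomerulus and an S1 library of 1 number come from the same rat is not given in the sources used here, and this fit treats them as independent. Benjamini-Hochberg adjustment was over all genes tested in a comparison, with a threshold of 0.05, and every log2 fold change, SE and adjusted p of a gene is edgeR's unless another tool is named. SE is the size of the log2 fold change divided by the square root of F.

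The comparisons, the gene lists (29, with 734 symbols, of which 711 were found), the rule for named genes and the first group of other settings were fixed before the data were examined. The 28 lists with at least 5 measured members were tested with camera of limma 3.58.1 at its preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. Camera with an estimated correlation, fry (which tests whether members move one way on balance and makes no comparison with other genes) and camera without members shared between lists were also run. Members past the threshold were counted over all genes and adjusted over the list alone.

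Genes were named by rule, from symbols other than LOC, RGD, AABR, ENSRNOG and Mir names with a mean of at least 5 CPM in the tissue: the 8 highest and 8 lowest past the threshold over all times with the same sign at the 3 times; the 3 highest and 3 lowest past it at each time; the 3 with the smallest adjusted p for a difference between times and 5 of each sign between the segments, if past it; up to 4 members with the smallest p of each list described, with no CPM minimum; and Mki67, Ccnd1, Myc, Igf1, Havcr1, Lcn2, Nphs1, Slc34a1, Slc5a2 and further fixed genes. Some genes that this rule names are not reported here.

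That first group held DESeq2 1.42.0, RLE size factors, no filter on low counts, limma with trend on log2(RPKM or FPKM + 1) for genes with a mean of at least 1, limma voom with sample quality weights, a replicate block, the 8 libraries of a time alone, a purity covariate for the dissected segments, and leaving out each library in turn. The limma run on RPKM or FPKM used no TMM factors, so libraries were scaled by their gene totals alone. Added after the data were seen were runs without the sham 24 h pair numbered 2 of glomeruli and S1 tubules; without the doubted libraries, which are that pair, the nephrectomy 72 h glomerulus library numbered 3 and the nephrectomy 72 h S1 library numbered 2; without the whole kidney 24 h libraries numbered 3 and 4; with a cortex covariate, the mean of the podocyte markers; and over 48 and 72 h only.

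The tests were tested on simulated data: negative binomial counts with each gene's mean and dispersion and the library sizes of the real samples, in which 200 genes of a comparison were changed by 1.5, 2 or 4-fold. Over all times edgeR found 58.2, 85.1 and 95.5% of them in whole kidney (15426 genes tested), 3, 16.4 and 57.6% in S1 tubules (17582) and 0, 10.4 and 63.6% in glomeruli (20633). In whole kidney it found 17.9, 58.2 and 81.8% at 24 h (15511 genes), 10.4, 55.2 and 87.9% at 48 h (15374) and 19.4, 49.3 and 83.3% at 72 h (15388). In S1 tubules it found 0, 0 and 13.6% at 24 h (17499), 0, 0 and 15.2% at 48 h (17554) and 0, 1.5 and 24.2% at 72 h (17627), and in glomeruli 0, 0 and 15.2% (20614), 0, 1.5 and 13.6% (20459) and 0, 0 and 4.5% (20552). For a change at 24 h alone, tested as a difference between times, it found 4.5, 28.4 and 75.8% in whole kidney (15476), 0, 0 and 0% in S1 tubules (17755) and 0, 0 and 1.5% in glomeruli (20490), and for the difference between segments 0, 1.5 and 31.8% (21957). DESeq2 called 22, 32 and 28 unchanged genes over all times in whole kidney, S1 tubules and glomeruli (edgeR 6, 2 and 3) and 24, 15 and 11 between times (edgeR 0 in each), and it was not simulated at single times. Changes of 2-fold in the dissected segments were thus mostly not detectable with these libraries as labelled. The dispersions of the segments include the sham 24 h pair numbered 2, and no simulation was run without it, so its share in this is not known. For lists, 1 of 28 random lists was changed in simulated whole kidney data: camera found it with either correlation and called 0 of the others, and fry found it and called 1 other. The simulated genes varied independently, so this does not test how camera's preset correlation behaves on real lists, whose genes vary together.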

Results

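RNA was sequenced from the left kidney of adult male Sprague-Dawley rats, an outbred laboratory strain, 24, 48 or 72 h after the right kidney had been removed (nephrectomy) or after a sham operation that left it in place. Loss of a kidney is a classical stimulus for growth of the remaining one, and the design asks how its transcripts differ from those after sham surgery. Samples were of 3 kinds: microdissected glomeruli, the filtering capillary tufts; microdissected S1 segments, the first part of the proximal tubule; and the whole left kidney. The 72 libraries formed 18 groups of tissue, surgery and time with 4 libraries in each, 24 libraries per tissue.

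Counts assigned to genes ranged from 2.64 to 61.98 M (1e+06 counts) per library in glomeruli, with a median of 10.98 M. They ranged from 6.4 to 87.37 M in S1 tubules (median 23.38) and from 10.1 to 55.52 M in whole kidney (median 38.41). Genes in which at least 1 count fell numbered 24050 in the median glomerulus library, 21500 in S1 tubules and 18710 in whole kidney. The nephrectomy 72 h glomerulus library numbered 3 was the shallowest, with 2.64 M gene counts that made up 2.9% of its uniquely placed reads. In the nephrectomy 72 h S1 library numbered 2 the share was 8%, against a median of 62.9% in S1 tubules. The spread between libraries of a group, as edgeR's common biological coefficient of variation, was 0.683 in glomeruli, 0.743 in S1 tubules and 0.248 in whole kidney.

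Marker genes separated the 3 kinds of sample. Levels are given as CPM, counts per 1e+06 gene counts scaled by TMM factors fitted within each labelled tissue. Podocyte markers, genes of the glomerular filter cells such as Nphs1, had a mean log2 CPM of 8.57 ± 1.05 (SD, n = 24) in glomeruli, 1.99 ± 1.04 in S1 tubules and 4.28 ± 0.49 in whole kidney. Proximal tubule transport genes stood at 2.69 ± 1.40, 6.67 ± 0.92 and 6.25 ± 0.51 in the same order. Endothelial markers followed the glomeruli (7.41 against 2.53 in S1 tubules), as did markers of mesangial and smooth muscle cells (6.08 against 0.53). Loop of Henle and distal tubule markers (5.89) and collecting duct markers (5.22) were high in whole kidney. They were low in both dissected segments, at 2.45 and 1.22 in glomeruli and 1.30 and 1.70 in S1 tubules. Immune cell markers had means of 4.23 in glomeruli, 1.61 in S1 tubules and 2.73 in whole kidney. A single pair stood apart: the library labelled glomeruli, sham 24 h, replicate 2 had a podocyte mean of 4.04 and a proximal mean of 8.72. The library labelled S1 tubules with the same surgery, time and number had 6.49 and 2.59. The TMM factors of these libraries were 0.315 and 3.574, so their levels depend on the scaling. On log2(CPM + 0.5) without TMM factors the means were 2.75 and 7.2 in the first and 8.33 and 4.46 in the second. On that scale other S1 libraries had podocyte means of 1.6 to 3.38 and proximal means of 5.8 to 7.36. Other glomerulus libraries had 8.09 to 9.14 and 1.74 to 4.54. Without this pair, called here the sham 24 h pair numbered 2, the podocyte means were 8.77 ± 0.41 in glomeruli and 1.80 ± 0.41 in S1 tubules (n = 23). Labels were kept as given, and list medians that this pair changes most are also given without it.

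**Figure D1:**
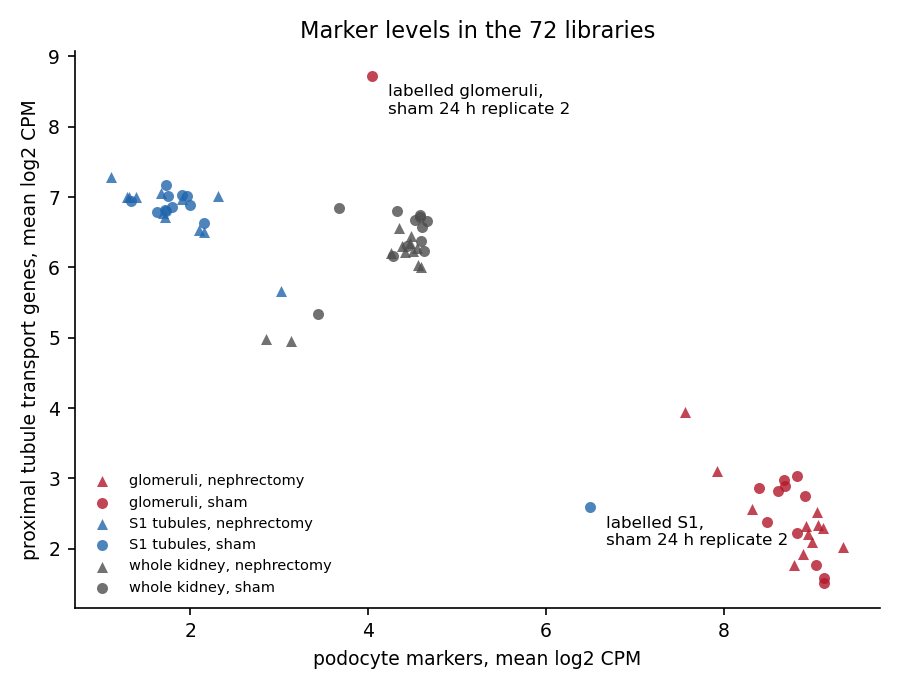
Mean log2 CPM of podocyte markers (horizontal axis) and of proximal tubule transport genes (vertical axis), 1 point per library, coloured by tissue, with triangles for nephrectomy and circles for sham. The libraries labelled glomeruli and S1 tubules, sham 24 h, replicate 2 lie at 4.04 and 8.72 and at 6.49 and 2.59, away from the other libraries of their tissues.

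In whole kidney 30 of 39 genes of DNA replication and mitosis and 13 of 25 of cholesterol synthesis rose after nephrectomy, relative to sham surgery, over the 3 times, and 3 of 36 proximal tubule transport genes fell. edgeR called 448 of 15678 genes at an adjusted p of 0.05, 265 higher and 183 lower, and 432 of them had the same sign at 24, 48 and 72 h. The highest named genes were Iqgap3, a scaffold protein of dividing cells (log2 fold change 1.56 ± 0.29, SE; adjusted p 0.0102), and the histone genes Hist1h3a (1.53 ± 0.32), Hist1h2ail1 (1.34 ± 0.30) and Hist1h4b (1.33 ± 0.34). They were followed by the kinetochore gene Kntc1 (1.33 ± 0.24), the DNA topoisomerase Top2a (1.32 ± 0.29), and the cytokinesis genes Prc1 (1.29 ± 0.27) and Kif20a (1.25 ± 0.25). Histone genes have near-identical copies, so their values are uncertain. Of 10 other settings Hist1h4b kept its call in 4 and Hist1h2ail1 in 8, and both lost it without the 24 h libraries numbered 3 and 4. Each of these 8 genes was above the sham mean of its time in 10 to 12 of the 12 nephrectomy libraries, which follows in part from their choice by fold change and sign. All nephrectomy libraries of a time lay above all its sham libraries at 1 or 2 of the 3 times. Top2a had 21.7 ± 11.6, 55.7 ± 54.6 and 44.1 ± 10.3 CPM (SD, n = 4) at 24, 48 and 72 h after nephrectomy, against 13.3 ± 5.74, 15.7 ± 4.89 and 16.5 ± 6.41 after sham surgery. At 48 h the nephrectomy library numbered 4 stood highest, with 135 CPM of Top2a against 16.2 to 50.1 in the other 3.

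The lowest named genes over the 3 times in whole kidney were F13b, a subunit of coagulation factor XIII (-2.47 ± 0.44; adjusted p 0.00792), the trypsin inhibitor Spink1 (-2.02 ± 0.43), Fam151a (-1.90 ± 0.48) and Spp2 (-1.82 ± 0.41). They were followed by the plasma protein gene Hrg (-1.65 ± 0.38), the proximal sulfate transporter Slc13a1 (-1.57 ± 0.24) and the cytochrome P450 Cyp2e1 (-1.52 ± 0.22; adjusted p 0.00472). Each was below the sham mean of its time in 11 or 12 of the 12 nephrectomy libraries, which again follows in part from their choice. All nephrectomy libraries of a time lay below all its sham libraries at 0 to 2 of the 3 times. Cyp2e1 had 44.4 ± 20.5, 78.3 ± 38.3 and 59.9 ± 7.69 CPM (SD, n = 4) after nephrectomy and 191 ± 88.9, 161 ± 52.6 and 161 ± 58.8 CPM after sham surgery at 24, 48 and 72 h. The 4 libraries at 24 h that were numbered 3 and 4, of both surgeries, stood apart. Slc5a2, of the early proximal tubule, had at most 1.86 CPM in them and at least 18.41 in the other 20 whole kidney libraries. Their podocyte means were 2.85, 3.13 and 3.43 (others 3.67 to 4.66) and their proximal transport means 4.98, 4.96 and 5.34 (others 6.01 to 6.85), except in sham replicate 4, which lay within both ranges (4.28 and 6.16). Mitochondrial genes took 71 to 80.6% of their gene counts (others 36 to 66.3%). Their TMM factors were 0.452 to 0.685 (others 0.835 to 1.572), and 93.9% of the reads of nephrectomy replicate 3 were not uniquely placed. The log2 fold changes of F13b were -4.44, -1.26 and -1.70 at 24, 48 and 72 h, those of Spink1 -4.05, -0.51 and -1.50, and those of Spp2 -3.70, -0.53 and -1.22. Over 48 and 72 h only, Slc13a1 (-1.29) and Cyp2e1 (-1.23) kept their calls and the other 5 lost theirs (-1.48 to -0.87).

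**Figure D2:**
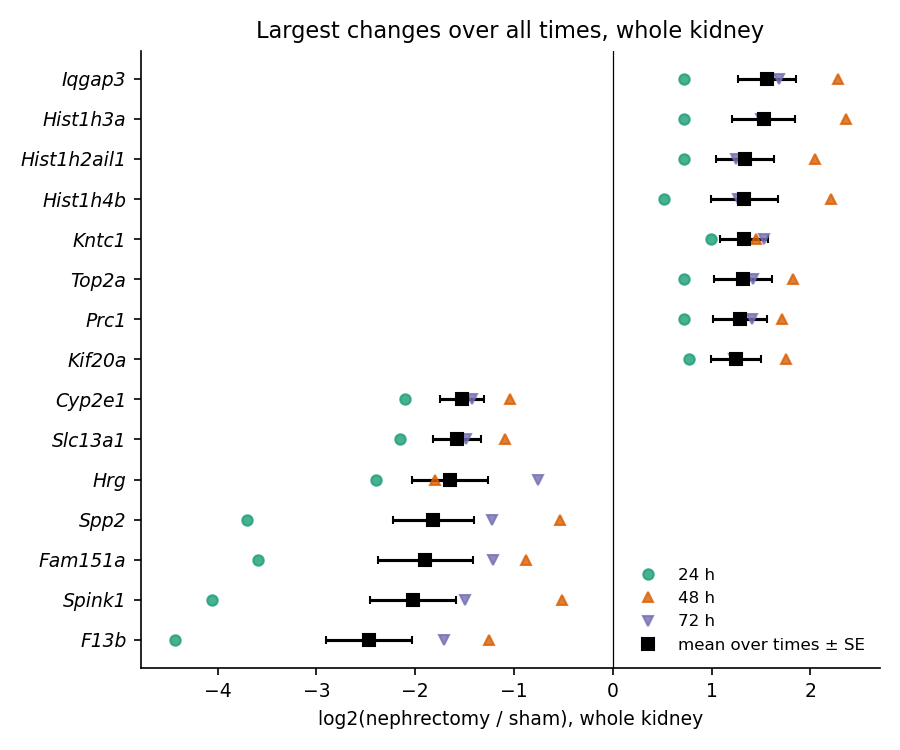
Log2 fold change (nephrectomy over sham) in whole kidney of the highest and lowest genes named above over the 3 times. Black squares are the mean over times with its SE and coloured symbols the single times, with F13b from -4.44 at 24 h to -1.26 at 48 h and Iqgap3 from 0.72 at 24 h to 2.28 at 48 h.

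The whole kidney count depended on the tool and on single libraries. DESeq2 called 865 genes, 446 of them shared, voom with sample quality weights 1884, and limma on log2(FPKM + 1) called 0, with 598 genes at an unadjusted p under 0.05. That limma run also lacked the TMM factors, which ranged from 0.452 to 1.572 in whole kidney. Its count thus differs in scaling as well as in tool, and the 2 were not tested apart. In edgeR 785 genes passed without the 24 h libraries numbered 3 and 4, and 154 over 48 and 72 h only. Leaving out 1 library moved the count beyond 1.5 times in 7 of 24 cases. It was 1068 without sham 24 h replicate 2, 296 without sham 72 h replicate 3 and 291 without nephrectomy 48 h replicate 3. It was 283 without nephrectomy 48 h replicate 4, 252 without sham 48 h replicate 2, 248 without nephrectomy 72 h replicate 4 and 242 without sham 72 h replicate 2.

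Among the gene lists in whole kidney over the 3 times, DNA replication and mitosis had the largest share of called members. Of its 39 members 30 rose and 9 did not pass, and 34 rose adjusted over the list alone. The list had a median log2 fold change of 1.04 (quartiles 0.70 to 1.21). camera called the list with its preset correlation and fry did too (adjusted p 0.0073), and the call was lost with an estimated correlation (adjusted p = 0.19 with an estimated correlation). Examples were the replication licensing genes Mcm6 (1.04 ± 0.17) and Mcm3 (1.03 ± 0.18), cyclin E1 (Ccne1, 1.40 ± 0.24) and the transcription factor E2f1 (1.12 ± 0.21). The proliferation marker Mki67 was higher by 1.15 ± 0.28 (adjusted p 0.0256). Its call did not hold whichever library was left out, and it was lost in limma on log2(FPKM + 1). In the list of G1 cyclins and CDK inhibitors edgeR called 0 of 14 members, against 1 adjusted over the list alone, and the median was 0.13. Its member with the smallest p was the CDK inhibitor Cdkn1a (0.82 ± 0.23, adjusted p 0.0611), and cyclin D1 (Ccnd1) differed by 0.17 ± 0.13.

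Cholesterol synthesis genes followed: 13 of 25 rose, 17 adjusted over the list alone, and the median was 0.51 (quartiles 0.22 to 0.63; adjusted p = 0.13 with an estimated correlation, 0.0018 in fry). They included the lanosterol demethylase Cyp51 (0.84 ± 0.10, adjusted p 0.000604), the sterol sensor Insig1 (0.90 ± 0.15), the isoprenoid enzyme Idi1 (0.63 ± 0.10) and Hmgcs1 (0.72 ± 0.13). Cyp51, the gene with the smallest adjusted p of all, was above the sham mean of its time in 12 of 12 nephrectomy libraries, which follows in part from its choice. Extracellular matrix genes had 4 of 35 members that rose, 11 adjusted over the list alone, and a median of 0.28 (adjusted p = 0.25 with an estimated correlation, 0.034 in fry). The 4 were the collagens Col5a1 (0.53 ± 0.13), Col4a1 (0.52 ± 0.13) and Col18a1 (0.52 ± 0.14) and the collagen crosslinking enzyme Loxl2 (0.41 ± 0.10). Over 48 and 72 h only, Cyp51 and Insig1 kept their calls, and Idi1 (0.29), Hmgcs1 (0.52) and these 4 (0.41 to 0.49) lost theirs. Of 10 other settings Col4a1 kept its call in 4 and Col5a1, Loxl2 and Col18a1 in 5. Glycolysis genes had a median of 0.23, with 0 of 16 members called by edgeR over all genes or adjusted over the list alone. Of them 13 were above 0. The list was called by camera at its preset correlation (adjusted p 0.0011) and in fry (0.034), and not with an estimated correlation (adjusted p = 0.25).

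Lists of proximal tubule function had medians below 0 in whole kidney. Of 36 proximal tubule transport genes 3 fell, 17 adjusted over the list alone, with a median of -0.33 (adjusted p = 0.13 with an estimated correlation, 0.0073 in fry): Slc13a1, the organic anion transporter Slc22a8 (-0.996 ± 0.216) and the scaffold Pdzk1 (-0.49 ± 0.11). Of 27 genes of fatty acid oxidation and PPAR targets 5 fell, 10 adjusted over the list alone (median -0.22, adjusted p = 0.25 with an estimated correlation, 0.034 in fry). Among the 5 were the pantetheinase Vnn1 (-1.21 ± 0.25), the mitochondrial dehydrogenases Hadh (-0.44 ± 0.10) and Acadm (-0.29 ± 0.07) and the fatty acid hydroxylase Cyp4a1 (-0.84 ± 0.20). In gluconeogenesis and fructose metabolism 2 of 12 genes fell, Fbp1 (-0.60 ± 0.14) and pyruvate carboxylase (Pc, -0.44 ± 0.12), and 4 adjusted over the list alone. The median was -0.46 (adjusted p = 0.34 with an estimated correlation, 0.088 in fry). The median of all genes tested was -0.01. The 24 h samples include the libraries low in proximal genes. Over 48 and 72 h only, Slc13a1 kept its call, and Slc22a8 (-0.37), Pdzk1 (-0.34), Vnn1 (-0.92), Hadh (-0.31), Acadm (-0.28), Cyp4a1 (-0.55), Fbp1 (-0.52) and Pc (-0.37) lost theirs in a contrast of fewer libraries. The medians of the 3 lists were then -0.22, -0.19 and -0.17. Of 10 other settings Pc kept its call in 3, Acadm in 4, Cyp4a1 and Fbp1 in 7, and Slc22a8, Pdzk1, Vnn1 and Hadh in 8. Pc and Acadm also lost theirs without the filter on low counts and with a cortex covariate, where no library is left out. The phosphate transporter Slc34a1 (-0.39 ± 0.14, adjusted p 0.132) and the glucose transporter Slc5a2 (-0.85 ± 0.60) did not pass, and neither did the podocyte gene Nphs1 (0.04).

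At 24 h 4 of 25 cholesterol synthesis genes and 3 of 17 glucocorticoid targets rose in whole kidney, and 3 of 36 proximal transporters fell. edgeR called 37 genes, 14 higher and 23 lower. The called genes named here all had their 4 nephrectomy libraries on 1 side of the sham mean, which follows in part from their choice. Zbtb16, a transcription factor induced by glucocorticoids, was the highest named gene (3.41 ± 0.60, adjusted p 0.0273), followed by the clock gene Per1 (1.61 ± 0.34) and Tsku (1.55 ± 0.32). Of 17 glucocorticoid targets 3 rose, Zbtb16, Per1 and Tsc22d3, with 8 higher and 1 lower adjusted over the list alone. The list's median was 0.44 with 12 above 0 (adjusted p = 0.098 with an estimated correlation, 0.00816 in fry). Without the libraries numbered 3 and 4, Per1 (1.33), Tsku (0.71) and Tsc22d3 (0.87) lost their calls. F13b (-4.44 ± 0.85), Spink1 (-4.05 ± 0.83) and Spp2 (-3.70 ± 0.77) were the lowest. All 25 cholesterol synthesis genes were above 0 with a median of 0.76, and 4 rose, 14 adjusted over the list alone. The 4 were Idi1 (1.30 ± 0.18), Cyp51 (1.06 ± 0.18), Hmgcs1 (1.11 ± 0.23) and Dhcr7 (1.06 ± 0.22; adjusted p = 0.098 for the list with an estimated correlation). Of 36 proximal transporters 3 fell, among them Slc22a8 (-2.24 ± 0.39) and Slc13a1 (-2.15 ± 0.43), and 17 adjusted over the list alone (median -0.52; adjusted p = 0.17 with an estimated correlation). The libraries numbered 3 and 4 are in both groups here, and the podocyte list had a median of 0.12 between nephrectomy and sham. Proximal transport means of replicates 1 to 4 were 6.01, 6.03, 4.98 and 4.96 log2 CPM after nephrectomy and 6.85, 6.80, 5.34 and 6.16 after sham surgery. Sham replicates 1 and 2 also had the highest Slc5a2 in whole kidney (282.5 and 127.5 CPM). Whether the lower proximal genes at 24 h stem from nephrectomy or from the tissue extracted was not tested.

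The 24 h count changed with every library left out: it was 9 without nephrectomy replicate 1, 1 without nephrectomy replicate 2, 1 without nephrectomy replicate 3 and 9 without nephrectomy replicate 4. It was 10 without sham replicate 1, 171 without sham replicate 2, 364 without sham replicate 3 and 137 without sham replicate 4. It was 2645 without the libraries numbered 3 and 4, 34 of them shared. That run sets 2 nephrectomy libraries against 2 sham libraries at 24 h, sham replicates 1 and 2, which had the highest Slc5a2 in whole kidney. A difference in the tissue extracted is thus not excluded for this count. The count was 307 in DESeq2 (84 higher and 223 lower) and 0 with the 8 libraries of 24 h alone.

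**Figure D3:**
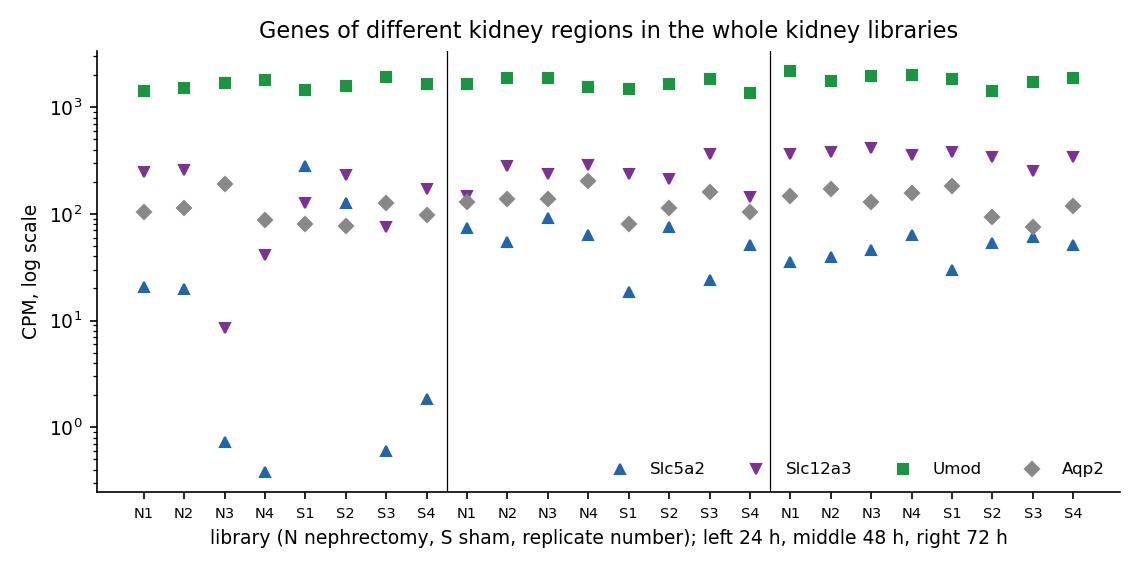
CPM on a log scale of genes of different kidney regions in the 24 whole kidney libraries: Slc5a2 (early proximal tubule), Slc12a3 (distal convoluted tubule), Umod (thick ascending limb) and Aqp2 (collecting duct). In the 24 h libraries N3, N4, S3 and S4 Slc5a2 had 0.723, 0.3788, 0.5983 and 1.86 CPM.

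At 48 h DNA replication and mitosis genes had a median of 1.42 in whole kidney (0.54 at 24 h and 1.13 at 72 h), and 34 of 39 rose adjusted over the list alone. Nephrectomy replicate 4 stood apart, with 142.7 CPM of Mki67 against 24.57 to 73.47 in the other 3. Without it the list's 48 h median was 0.63, and 1.32 to 1.69 without any other 48 h library. Over all 15678 genes edgeR called 0 (1619 at an unadjusted p under 0.05; DESeq2 166, voom with quality weights 6, limma on log2(FPKM + 1) 0). The list was not called with an estimated correlation (adjusted p = 0.45). Ccne1 (1.99 ± 0.41), the cyclin Ccna2 (1.74 ± 0.42) and Kif20a (1.75 ± 0.44) had the largest values among its members with the smallest p. Glucocorticoid targets went the other way from 24 h, with a median of -0.57 and 2 of 17 members above 0. This list kept its call (adjusted p = 0.027 with an estimated correlation, 0.0058 in fry). They included Sgk1 (-1.25 ± 0.21, adjusted p 0.0646), Klf9 (-0.93 ± 0.17) and Zbtb16 (-2.34 ± 0.56). Tubular injury genes had a median of 0.54, with 8 of 21 higher adjusted over the list alone (adjusted p = 0.46 with an estimated correlation). Havcr1, the injury marker KIM-1, had 8.95 ± 13.2 CPM after nephrectomy and 0.747 ± 0.181 after sham surgery (SD, n = 4), with 28.6 CPM in nephrectomy replicate 4 and 0.403 to 3.56 in the other 3. The count of 0 became 151 without nephrectomy replicate 2 and 6 without nephrectomy replicate 1.

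At 72 h edgeR called a single gene in whole kidney, Sgk1, a kinase induced by glucocorticoids and aldosterone. It stood at 142 ± 39.3 CPM after nephrectomy and 56.2 ± 12.7 after sham surgery (SD, n = 4; log2 fold change 1.34 ± 0.21, adjusted p 0.0245). It was lost with a replicate block and without nephrectomy replicate 3 or 4 or sham replicate 2, 3 or 4 (0 called in each). limma on log2(FPKM + 1) called Zbtb16 and not Sgk1. By contrast, 596 genes passed in voom with quality weights and 281 with the 8 libraries of 72 h alone. Of the DNA replication list 28 members rose adjusted over the list alone (adjusted p = 0.12 with an estimated correlation), with Cdc45 at 1.39 ± 0.41 and E2f1 at 1.23 ± 0.37. Cholesterol synthesis genes had a median of 0.43 (adjusted p = 0.12 with an estimated correlation), and Cyp51 stood at 0.85 ± 0.18.

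**Figure D4:**
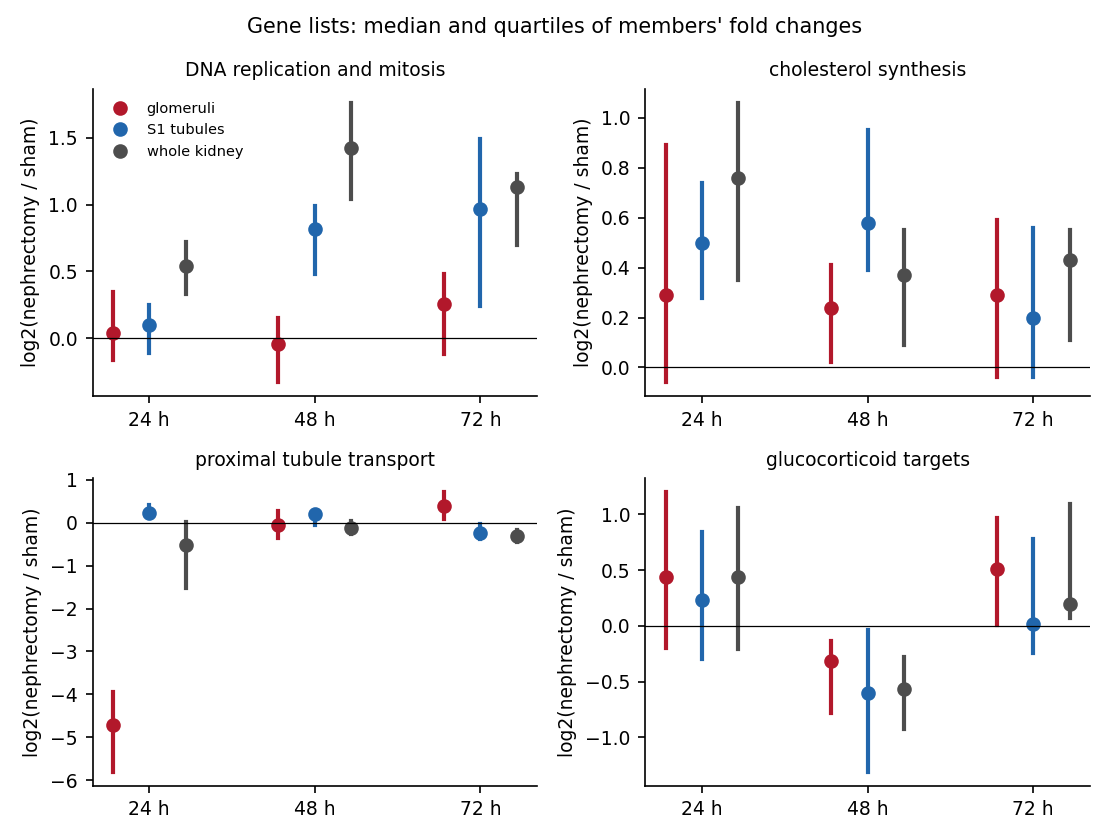
Median (points) and quartiles (bars) of the members' log2 fold changes (nephrectomy over sham) for 4 gene lists at 24, 48 and 72 h in each tissue. The glucocorticoid target list in whole kidney has medians of 0.44, -0.57 and 0.20.

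The effect of nephrectomy in whole kidney differed between times for 3 genes, all members of the glucocorticoid target list. These were Sgk1 (adjusted p 0.000252), Zbtb16 (0.00349) and Tsc22d3 (0.00349), by edgeR's test of the difference. Their log2 fold changes at 24, 48 and 72 h were 0.88, -1.25 and 1.34 for Sgk1, 3.41, -2.34 and 2.84 for Zbtb16, and 1.05, -0.86 and 1.09 for Tsc22d3, the gene of the glucocorticoid-induced leucine zipper. In sham libraries Sgk1 had 64.3 ± 4.18, 184 ± 33.6 and 56.2 ± 12.7 CPM at the 3 times, and in nephrectomy libraries 118 ± 34.8, 77.6 ± 10.9 and 142 ± 39.3 (SD, n = 4). The count was 18 without sham 24 h replicate 2, 5 without sham 24 h replicate 3 and 7 without sham 48 h replicate 2, 51 in DESeq2, and 1830 without the 24 h libraries numbered 3 and 4.

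**Figure D5:**
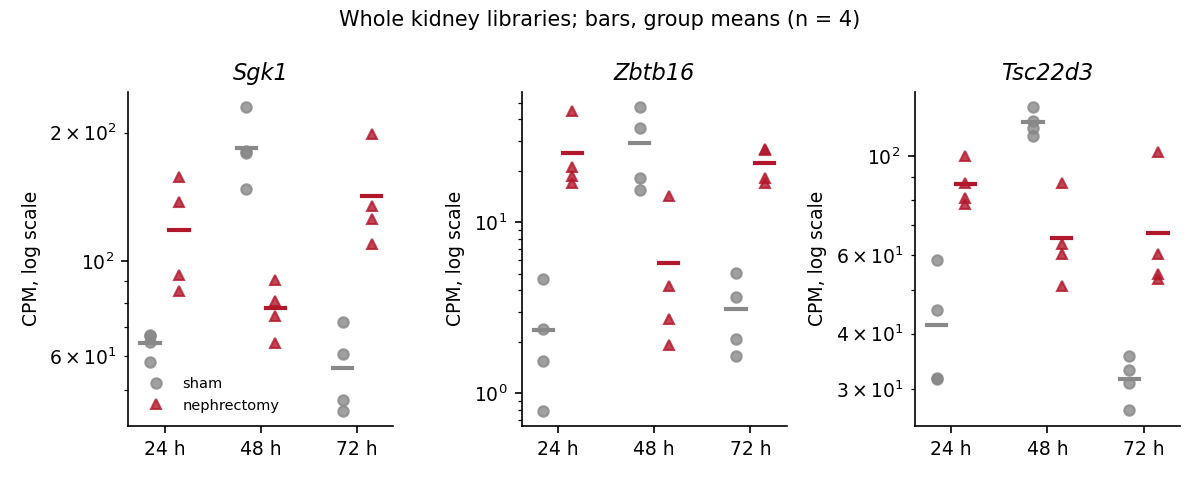
CPM on a log scale of Sgk1, Zbtb16 and Tsc22d3 in the whole kidney libraries at 24, 48 and 72 h, sham as grey circles and nephrectomy as red triangles, with bars at the group means (n = 4). The Sgk1 mean after sham surgery is 64.3, 184 and 56.2 CPM and after nephrectomy 118, 77.6 and 142 CPM.

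In S1 tubules the DNA replication and mitosis list was higher after nephrectomy over the 3 times, without a single gene passing the test. Of its 39 members 37 were above 0, with a median of 0.62 (quartiles 0.39 to 0.81). It was the list called by camera in this comparison that kept its call (adjusted p = 0.048 with an estimated correlation). It was not called in fry (adjusted p 0.27) or without the sham 24 h pair numbered 2 (median 0.70; adjusted p = 0.091 with an estimated correlation). Adjusted over the list alone 2 members passed. Values were 1.06 ± 0.27 for Mki67, 1.05 ± 0.36 for the mitotic cyclin Ccnb1, 0.94 ± 0.27 for Top2a and 0.68 ± 0.22 for the spindle gene Tpx2. By time the list's medians were 0.10, 0.82 and 0.97. Collecting duct markers, of a cell type outside this segment, were above 0 in 15 of 15 cases with a median of 0.44, and 0.34 without the pair (adjusted p = 0.75 with an estimated correlation). Their medians by time were 1.09, 0.62 and -0.39. Mki67 had 26.8 ± 11.6, 59.2 ± 33.9 and 73.2 ± 29.1 CPM after nephrectomy and 18.0 ± 9.56, 28.6 ± 8.83 and 24.96 ± 6.998 CPM after sham surgery at 24, 48 and 72 h (SD, n = 4). Cholesterol synthesis genes had a median of 0.40 with 23 of 25 above 0, 3 of them past the threshold adjusted over the list alone (adjusted p = 0.13 with an estimated correlation). Members included Cyp51 at 0.91 ± 0.23, Idi1 at 0.79 ± 0.29 and Insig1 at 0.73 ± 0.22. Proximal tubule transport genes, the segment's own, had a median of 0.06, and Slc34a1 (-0.08) and Slc5a2 (-0.06) were near 0. These values include the library labelled sham 24 h replicate 2, with 48.02 CPM of Slc34a1 and 3.19 CPM of Slc5a2. The other sham 24 h libraries had 3630 to 4203 and 97.42 to 135 CPM.

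Of 18124 genes tested in S1 tubules, edgeR called 0 over the 3 times (393 at an unadjusted p under 0.05; DESeq2 3, voom with quality weights 0, limma on log2(RPKM + 1) 0). At 24 h it called 0 (738; DESeq2 9, voom 0, limma 0) and at 48 h 0 (302; DESeq2 4, voom 178, limma 0). It called at 72 h 0 (1821; DESeq2 438, voom 1, limma 0) and for a difference between times 0 (1455; DESeq2 6, voom 7, limma 0). The 3 genes of DESeq2 over all times were Sema6d, LOC680646 and Csmd1 and the 4 at 48 h LOC680646, Mageb4, Sh3rf1 and Zbtb16, named after their values were seen. In simulated S1 data DESeq2 called 32 unchanged genes over all times, and edgeR 2. At 72 h the smallest adjusted p was that of Sgk1 (2.84 ± 0.53, adjusted p 0.293), which passed without nephrectomy replicate 2, the library with 8% of unique reads in genes (1 gene called). Without it 4 genes passed for a difference between times (Sgk1, Plk3, Per1 and Sh3rf1), and 2 without the library labelled sham 24 h replicate 2 (Sgk1 and Plk3), all named after their values were seen. The podocyte list had a median of -0.84 over the 3 times, that of mesangial and smooth muscle cells -0.81 and the endothelial list -0.45 (adjusted p = 0.73 with an estimated correlation for each). Without the sham 24 h pair numbered 2 these medians were 0.14, -0.03 and 0.04.

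In glomeruli the DNA replication and mitosis genes had a median of 0.05 over the 3 times with 24 of 39 above 0. The median of all genes tested was -0.07. Camera called the list higher at its preset correlation (adjusted p 0.047). It was not called with an estimated correlation (adjusted p = 0.69) or in fry (adjusted p 0.94). Mki67 stood at 0.19 ± 0.26. Cholesterol synthesis genes had a median of 0.30 and 17 of 25 above 0 (adjusted p = 0.21 with an estimated correlation; median 0.42 without the sham 24 h pair numbered 2). Members included Cyp51 at 0.69 ± 0.21, Hmgcs1 at 0.77 ± 0.25 and Insig1 at 0.70 ± 0.28. Immediate early genes, induced within minutes by many stimuli, were above 0 in 18 of 18 cases with a median of 0.62 (adjusted p = 0.28 with an estimated correlation), which was 0.53 without the pair. Extracellular matrix genes had a median of 0.21 (adjusted p = 0.28 with an estimated correlation), with the matricellular gene Ctgf at 0.94 ± 0.31. Podocyte markers had a median of 0.14, and Nphs1 was at 0.14. Both values include the library labelled sham 24 h replicate 2, which had 26.69 CPM of Nphs1 against 1117, 2645 and 2285 in the other sham 24 h libraries. Proximal tubule transport genes in the glomerulus libraries had a median of -1.46 over the 3 times and -4.71 at 24 h, with 23 of 36 lower adjusted over the list alone over the 3 times (adjusted p = 0.69 with an estimated correlation). Without the pair the medians were 0.16 and 0.07.

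Of 21415 genes tested in glomeruli, edgeR called 0 over the 3 times (733 at an unadjusted p under 0.05), at 24 h (1596), at 48 h (184), at 72 h (330) and for a difference between times (821). DESeq2 called 0, 7, 1, 0 and 3 genes in the same order, voom with quality weights 0, 1, 0, 0 and 6, and limma on log2(RPKM + 1) 0 in each. Of these, Fkbp5 was the voom gene at 24 h, Fam111a the DESeq2 gene at 48 h, and Zbtb16, Nfil3 and Rgcc the 3 that differed between times in DESeq2, all named after their values were seen. So were the 7 of DESeq2 at 24 h, Pcbd1, Slc6a20, Fxyd2, RGD1305347, Fam83g, Mpv17l and Chpt1. All were lower (-5.07 to -3.44), against sham libraries that include the library of the pair, and Slc6a20 is a proximal transport gene. DESeq2 was not run without the pair, so these calls cannot be put down to nephrectomy. In simulated glomerulus data DESeq2 called 11 unchanged genes between times, and edgeR 0. The 24 h count was 507, 506 and 549 without sham replicate 1, 3 or 4, which leave the library of the pair as 1 of 3 sham libraries, and 364 without the filter on low counts. The count for a difference between times was 1 without the library labelled sham 24 h replicate 2 (Fkbp5, named after its values were seen).

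The effect of nephrectomy was not shown to differ between glomeruli and S1 tubules for any of 23776 genes tested. edgeR called 0 (942 at an unadjusted p under 0.05), as did DESeq2, voom with quality weights and limma on log2(RPKM + 1). DNA replication and mitosis genes had a median difference of -0.40, glomeruli minus S1 tubules (adjusted p = 0.39 with an estimated correlation; -0.49 without the sham 24 h pair numbered 2), with Ccnb1 at -1.11 ± 0.47. Immediate early genes had a median of 1.22 (adjusted p = 0.39 with an estimated correlation; 0.52 without the pair). Podocyte markers had a median of 1.51 (adjusted p = 0.40 with an estimated correlation) and proximal transport genes -1.56 (adjusted p = 0.53 with an estimated correlation), which became -0.01 and 0.25 without the pair. For cholesterol synthesis the median difference was -0.13 (adjusted p = 0.92 with an estimated correlation).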

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

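The tests of the 3 patterns weighed in this part, and the runs without the pair, without the 24 h libraries numbered 3 and 4 and with a cortex covariate, were chosen after the result was seen. A library far from the other 3 of its group was found in 11 of 72 searches, which took several measures in the same 18 groups. Chance gives about 1 in 20, or 3.6 if the searches were independent, which they were not: 5 of the 11 fell on the sham 24 h pair numbered 2.

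Total gene counts (in M, 1e+06 counts) stood far from the rest of the group in glomeruli, nephrectomy 24 h, replicate 1 (36.22 M, others 10.57 to 11.97), in S1 tubules, nephrectomy 48 h, replicate 2 (72.83 M, others 22.7 to 23.82) and in the library labelled glomeruli, sham 24 h, replicate 2 (61.98 M, others 7.5 to 13.34). The proximal tubule transport mean was 7.06 log2 CPM in S1 tubules, nephrectomy 48 h, replicate 4, with the other 3 at 7 after rounding, and 1.77 in glomeruli, sham 72 h, replicate 4 (others 2.82 to 3.03). In whole kidney Zbtb16 had 44.69 CPM in nephrectomy 24 h replicate 3 (others 16.86 to 20.97), and Tsc22d3 had 102.1 CPM in nephrectomy 72 h replicate 4 (others 52.97 to 60.42).

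The library labelled glomeruli, sham 24 h, replicate 2 had a podocyte mean of 4.04 log2 CPM (others of its group 8.39 to 8.91) and a proximal mean of 8.72 (2.22 to 2.87), and the library labelled S1 tubules of that number had 6.49 (1.62 to 1.72) and 2.59 (6.79 to 6.82). These values are scaled by TMM factors (0.315 and 3.574 in the pair), and the log2(CPM + 0.5) values that follow are not. RNA of both segments mixed in the pair was not excluded: on log2(CPM + 0.5) the library labelled glomeruli had a podocyte mean of 2.75 (other S1 libraries up to 3.38, or 2.55 without nephrectomy 72 h replicate 2) and the library labelled S1 tubules a proximal mean of 4.46 (other glomerulus libraries up to 4.54, or 3.59 without nephrectomy 72 h replicate 3), so the bounds rest on 1 library each, with few reads in genes; the bounds without these libraries were added with the values known. Exchanged labels of the pair may account for it: across genes the library labelled glomeruli correlated at 0.988 with the S1 mean and 0.753 with the glomerulus mean, and the other at 0.945 with the glomerulus mean and 0.739 with the S1 mean, a smaller difference of 0.206. Where such an exchange would have arisen stays open, and no biological explanation was tested. Without the pair the proximal genes in glomeruli had a median log2 fold change of 0.16 over the 3 times and the podocyte markers in S1 tubules 0.14.

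In whole kidney the 24 h libraries numbered 3 and 4 of both surgeries had at most 1.86 CPM of Slc5a2 (other 20 libraries at least 18.41), and all but sham replicate 4 (4.28 and 6.16 log2 CPM) were below the others in podocyte markers (2.85 to 3.43, others 3.67 to 4.66) and proximal transport genes (4.96 to 5.34, others 6.01 to 6.85). Of loop and distal genes Slc12a3 (-2.51) and Calb1 (-2.39) were lower in the 4 than in the others and Umod (0.06) and Slc12a1 (0.90) were not, and the 4 had the highest mitochondrial shares (71 to 80.6%, others at most 66.3%) and the lowest TMM factors (0.452 to 0.685, others at least 0.835). Loss of transcripts by length was tested first with a bound of 1 log2 unit, which the podocyte markers did not reach (median -0.68 against 200 genes nearest in length and level). The bound was then rewritten with that value known. The upper quartile was -0.10, and the list's own median of -0.57 lay below the medians of all 10 length classes (-0.22 to 0.15). The podocyte markers were thus lower than most genes of like length, but a bound set with the value known cannot exclude loss by length. Less cortex in the tissue extracted may account for the pattern and cannot be told apart from a library batch or a difference in RNA quality, since collecting duct genes, which the medulla also holds, differed by 0.07, sham replicate 4 lay within the podocyte range of the others, and the kit and RNA quality of each library are not given in the sources used here. No biological explanation was tested, and edgeR called 2645 genes at 24 h without these libraries and 76 with a cortex covariate, against 37. Without them only replicates 1 and 2 of each surgery are left at 24 h.

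The effect of nephrectomy in whole kidney differed between 24, 48 and 72 h for Sgk1 (adjusted p 0.0002515), Zbtb16 (0.003485) and Tsc22d3 (0.003485) in edgeR's test of the difference, each with a positive effect at 24 and 72 h and a negative one at 48 h. A different clock phase at collection in the nephrectomy and sham groups cannot be told apart from an effect of nephrectomy on the clock: clock genes in phase with Arntl and those in phase with Dbp had medians of opposite sign in 9 of 9 comparisons (difference at 24, 48 and 72 h 1.16, -0.90 and 2.01 in whole kidney, 1.15, -1.08 and 2.20 in S1 tubules, 0.77, -2.23 and 2.50 in glomeruli), but which sign fell at which time was observed, not predicted. That difference passed between the sham groups of the 3 times in 0 of 3 tissues (exact permutation tests, n = 4 per time, adjusted p 0.0566 in glomeruli, 0.0566 in S1 tubules and 0.0854 in whole kidney), although sham means that range over more than the largest SD of a sham group, a looser bound tried first, were found in 3 of 3. For the clock genes the dissected segments had the sign of whole kidney in 6 of 6 comparisons. This argues against a different mix of kidney regions as the only source of that sign, although the bound was set with the signs known. The segments may come from the same rats, and a part of such a mix in the whole kidney values is not excluded. For the glucocorticoid targets a different mix cannot be told apart. Their 48 h effect minus the mean of the other effects had a median of -1.01 in S1 tubules with quartiles of -1.58 and 0.18. The hour of collection is not given in the sources used here, and an effect of nephrectomy itself on the clock or on glucocorticoids stays open, as untested.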

How the results depend on the processing

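The runs without the sham 24 h pair numbered 2, without the doubted libraries, without the 24 h libraries numbered 3 and 4, with a cortex covariate and over 48 and 72 h only, and the list counts with RLE size factors, were chosen after seeing the data; the rest were planned. Of 64 calls of named genes in whole kidney, 0 turned their direction under any alternative; 64 stayed past the threshold in DESeq2, 64 with RLE size factors, 60 without a filter, 56 with a replicate block, 55 with a cortex covariate, 52 without the 24 h libraries numbered 3 and 4, 48 in voom with sample quality weights, 34 whichever library was left out, 19 of 46 over 48 and 72 h only, 2 of 63 in limma on log2(FPKM + 1), and 1 of 15 with the 8 libraries of a time alone. The limma run on log2(FPKM + 1) used no TMM factors, so it changed the scaling as well as the tool. Of 1427 values of named genes that did not pass the threshold in the main test, 1130 kept their sign in every setting and 297 did not. In at least 1 other setting 209 of the 1427 passed it. The planned run without libraries under 1e+06 gene counts had 0 libraries to leave out and was not run. The number of genes called is limited by the spread between libraries, and for the changed counts below the cause was not tested, except that leaving out libraries or times leaves fewer samples.

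Counts of genes beyond 1.5 times the main count were as follows. DESeq2 called 7, 1 and 3 genes in glomeruli at 24 h, at 48 h and for a difference between times, 9, 4, 438, 3 and 6 in S1 tubules at 24, 48 and 72 h, over all times and between times (0 in edgeR for each), and 307, 166, 7, 865 and 51 in whole kidney in that order (37, 0, 1, 448 and 3 in edgeR). Voom with sample quality weights called 1 in glomeruli at 24 h and 6 between times, 178, 1 and 7 in S1 tubules at 48 h, 72 h and between times, and 110, 6, 596, 1884 and 26 in whole kidney. limma on log2(RPKM or FPKM + 1) called 1, 0 and 1 in whole kidney at 24 h, over all times (598 at an unadjusted p under 0.05) and between times. Without a filter on low counts edgeR called 364 in glomeruli at 24 h and 56, 1 and 5 in whole kidney at 24 h, 48 h and between times. With the 8 libraries of a time alone it called 2 in S1 tubules at 48 h, 0 in whole kidney at 24 h and 281 at 72 h. A replicate block gave 124 in whole kidney at 24 h and 0 at 72 h. Libraries of 1 number were correlated after each gene's group mean was subtracted. In whole kidney, nephrectomy with sham gave over 0.1 in 6 of 12 cases, at 0.12 to 0.29 at 72 h. The best match among the 4 sham libraries of the time had the same number in 3 of 12 cases, where chance gives 1 in 4. Glomerulus with S1 libraries gave over 0.1 in 10 of 24 cases, with the best match of the same number in 9. For the difference between the segments a replicate block, like edgeR without it, DESeq2, voom and limma, called 0 (173 at an unadjusted p under 0.05, against 942 without it). RLE size factors gave 2 between times in S1 tubules. A purity covariate gave 1 between times in glomeruli, and 1 at 48 h and 3 between times in S1 tubules. Without the sham 24 h pair numbered 2 there were 1 between times in glomeruli and 2 in S1 tubules, and without the doubted libraries 1 at 24 h and 2 between times in glomeruli, and 1, 1, 1 and 5 in S1 tubules at 48 h, 72 h, over all times and between times. In whole kidney the run without the 24 h libraries numbered 3 and 4 called 2645, 4, 2, 785 (288 shared) and 1830, a cortex covariate gave 76 at 24 h and 1 at 48 h, and 48 and 72 h only gave 154 (145 shared). The run without numbers 3 and 4 leaves 2 nephrectomy and 2 sham libraries at 24 h.

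Leaving out 1 library gave 0 to 549 genes in glomeruli at 24 h and 0 to 1 between times, 0 to 1 in S1 tubules at 72 h and 0 to 4 between times, and in whole kidney 1 to 364 at 24 h, 0 to 151 at 48 h, 0 to 1 at 72 h, 242 to 1068 over all times and 3 to 18 between times. The counts for the other comparisons stayed at 0. The genes behind the counts of 5 or fewer, named after their values were seen, were in glomeruli Fkbp5 at 24 h (voom and without the doubted libraries), Fam111a at 48 h (DESeq2), and between times Zbtb16, Nfil3 and Rgcc (DESeq2), Fkbp5 (purity covariate and without the pair), and Zbtb16 and Fkbp5 (without the doubted libraries). In S1 tubules they were Pex11a at 48 h (purity covariate, without the doubted libraries, and with Myo19 in the 8 libraries alone), Sgk1 at 72 h (voom and without the doubted libraries) and over all times (without the doubted libraries). DESeq2 had LOC680646, Mageb4, Sh3rf1 and Zbtb16 at 48 h and Sema6d, LOC680646 and Csmd1 over all times. Between times in S1 tubules they were Sgk1 and Plk3 (RLE and without the pair), with Pex11a (purity covariate) or Per1, Zbtb16 and Sh3rf1 (without the doubted libraries). In whole kidney they were Zbtb16 at 24 h and between times (limma), Sgk1 at 48 h (no filter and cortex covariate), Ipmk, Sgk1, Osbpl8 and Sdc1 at 48 h and Sgk1 and Insig1 at 72 h (without the 24 h libraries numbered 3 and 4), and between times Sgk1, Zbtb16, Tsc22d3, Ctgf and Per1 (no filter).

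Lists called by camera numbered 16, 4, 7 and 15 in glomeruli at 24, 48 and 72 h and over all times, 16, 6, 8 and 12 in S1 tubules, 12, 9, 12 and 10 in whole kidney and 15 for the difference between segments. With an estimated correlation they were 0 in each, except 1 in S1 tubules over all times and 1 in whole kidney at 48 h, and in fry 0 in each, except 3 at 24 h, 1 at 48 h and 6 over all times in whole kidney. Leaving out 1 library gave 1 to 9 at 48 h and 1 to 14 at 72 h in glomeruli, 6 to 20, 7 to 11, 3 to 9 and 4 to 18 in S1 tubules, and 9 to 18 between the segments. A purity covariate gave 6 at 24 h and 7 over all times in glomeruli, and 9 and 11 at 24 and 48 h in S1 tubules. Without the pair there were 6 in S1 tubules at 24 h, and without the doubted libraries 17 in glomeruli at 72 h and 10, 11 and 5 in S1 tubules at 24 h, 48 h and over all times. RLE size factors gave 10 in S1 tubules at 48 h.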

Other observations

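In this part the test on the kidney genes in the dissected segments and all counts of splits were planned, and the settings without libraries were chosen after the result was seen. Of the 448 genes called in whole kidney over the 3 times, 423 were tested in S1 tubules and 333 of them had the same sign there (78.7%), while in glomeruli 318 of 433 did (73.4%). The genes higher in whole kidney had a median log2 fold change of 0.55 in S1 tubules (212 of 241 above 0) and 0.08 in glomeruli (154 of 254), and the lower ones -0.05 in S1 tubules (121 of 182 below 0) and -0.49 in glomeruli (164 of 179). A share as large on one side, whether with the whole kidney sign or against it, came from 7 of 56 splits of the S1 libraries (largest other 89.6%). For glomeruli it came from 18 of 56 (largest other 82%), so chance was not excluded for either. Splits with the whole kidney sign alone were not counted apart. Without the sham 24 h pair numbered 2 the same sign was seen for 376 of 424 in S1 tubules (88.7%) and 225 of 437 in glomeruli (51.5%). The higher genes then had medians of 0.61 in S1 tubules and 0.09 in glomeruli, and the lower ones -0.16 and 0.07.

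Several gene groups tied to growth or energy use had small median changes in whole kidney. Of 64 ribosomal protein genes 1 fell, Rpl35 (-0.47 ± 0.09, adjusted p 0.0114), 1 adjusted over the list alone, with a median of -0.11 (adjusted p = 0.63 with an estimated correlation). Of 28 ribosome biogenesis genes 1 fell, Npm1, a nucleolar histone chaperone (-0.35 ± 0.10, adjusted p 0.0488), 3 adjusted over the list alone (median -0.08, adjusted p = 0.56 with an estimated correlation). In these 2 lists 51 of 64 and 21 of 28 members were below 0. Camera at its preset correlation called both lower (adjusted p 0.0069 and 0.026), and fry called neither (adjusted p 0.42 for each). Respiratory chain genes had a median of -0.02, growth factors and receptors -0.10, ATF4 and amino acid synthesis genes 0.07, and immune cell markers -0.04, with 0 members called by edgeR in each. Igf1 (0.04) and Myc (-0.10) were near 0, and the injury markers Lcn2 (0.68 ± 0.40) and Havcr1 (0.94 ± 0.49) did not pass. Single members rose in lists of other cell types: Tagln, a smooth muscle gene (0.67 ± 0.12, adjusted p 0.00792), the vasopressin receptor Avpr2 (0.47 ± 0.10, adjusted p 0.0141) and the potassium channel Kcnj10 (0.48 ± 0.13, adjusted p 0.0453). The clock genes Dbp (-0.70 ± 0.17, adjusted p 0.0277) and Hlf (-0.56 ± 0.14, adjusted p 0.0304) fell as the mean of the 3 times. Dbp was below the sham mean of its time in 9 of 12 nephrectomy libraries and Hlf in 11. Over 48 and 72 h only, Rpl35 (-0.52) and Tagln (0.77) kept their calls, and Npm1 (-0.29), Avpr2 (0.44), Kcnj10 (0.32), Dbp (-0.50) and Hlf (-0.54) lost theirs in a contrast of fewer libraries. Of 10 other settings Npm1 kept its call in 3, Kcnj10 in 4, Hlf in 6, Dbp in 7 and Avpr2 in 8. Npm1 and Kcnj10 also lost theirs without the filter on low counts and with a cortex covariate, where no library is left out.

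Other splits of the samples were compared with the real one. The counts of splits include the real one, so 1 of 56 means that only the real split was as large. This was so for the 448 genes of whole kidney over all times (highest other 18) and for the median of cholesterol synthesis in whole kidney (0.51, highest other -0.26). It was also so for the median of the DNA replication and mitosis list in whole kidney (1.04, highest other -0.60) and S1 tubules (0.62, highest other 0.41). No smaller share than 1 of 56 was possible, and the shares were not adjusted over the comparisons, so chance was made less likely and not excluded. Other splits were as large for cholesterol synthesis in S1 tubules (0.40, 5 of 56, highest other -0.46) and glomeruli (0.30, 5 of 56, highest other 0.49). They were also as large for DNA replication and mitosis in glomeruli (0.05, 41 of 56, highest other 0.28).

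For the other counts above 0, other splits were as large as the real one. In whole kidney 12 of 35 splits gave at least 37 genes at 24 h (highest other 1828), 2 of 35 at least 1 at 72 h (highest other 1) and 4 of 56 at least 3 between times (highest other 59). Where edgeR's real count was 0, every split is as large by construction, which says nothing about chance. This held for 35 of 35 splits in whole kidney at 48 h (highest other 1). In glomeruli the counts were 35 of 35 at 24 h (highest other 597), 48 h (0) and 72 h (0), and 56 of 56 over all times (1) and between times (237). In S1 tubules they were 35 of 35 at 24 h (highest other 0), 48 h (2) and 72 h (709), and 56 of 56 over all times (11) and between times (8). For the difference between the segments 22 of 22 were as large as 0 (highest other 6). Splits that call many genes point to a structure of the samples, of more than 1 kind in whole kidney at 24 h, where 13 of 35 splits had calls. The largest there were 1828 for nephrectomy 1 and 4 with sham 3 and 4 against the rest, 1725 for nephrectomy 1 and 2 with sham 3 and 4, and 1445 for nephrectomy 1 and 3 with sham 1 and 2. Numbers 1 and 2 against 3 and 4 of both surgeries gave 925 genes there and 597 in glomeruli at 24 h, and nephrectomy 1 and 3 with sham 2 and 4 against the rest gave 709 in S1 tubules at 72 h.

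For the number of lists called by camera at its preset correlation, chance was not excluded in any comparison. In glomeruli 22, 30 and 23 of 35 splits were as large at 24, 48 and 72 h (real 16, 4 and 7; highest other 20, 12 and 18) and 23 of 56 over all times (15; 22). In S1 tubules they were 12, 21 and 18 of 35 (real 16, 6 and 8; highest other 20, 10 and 16) and 23 of 56 (12; 19). In whole kidney they were 9, 12 and 10 of 35 (real 12, 9 and 12; highest other 15, 13 and 16) and 12 of 56 (10; 16), and between the segments 9 of 22 (15; 20).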
